A study of Mus musculus with 6 samples.

How the data were processed

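RNA was measured in 4T1 cells, a mouse mammary carcinoma line, in 3 control samples and 3 samples treated with gold, molybdenum disulfide and bismuth sulfide heterojunction particles plus near-infrared light. Groups and replicate numbers were taken from the sample labels, which also give all 6 samples 1 shared batch label. Per the labels' protocols, 3 µg of RNA per sample was selected on poly-T beads, fragmented, copied with random hexamers, selected for fragments of 150 to 200 bp, amplified and sequenced as paired 150 bp reads. The aligner, the read counter, the genome build, the annotation and the strand setting are not given in the sources used here. The labels say that RNA from cells of 3 individuals was pooled, and they do not say whether the samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

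The authors deposited 1 value per gene and sample in FPKM, per the file headers, for 56748 Ensembl mouse genes in the same order in every file. A symbol was found for 52073 of these identifiers in GENCODE M21. Of the other 4675, those that passed the filter were tested without a name. The FPKM of an identifier without a symbol added up to between 1.99% and 5.16% of a library. Coordinates, lengths, GC content and overlapping genes were looked up by identifier in GENCODE M21 on GRCm38, which may not be the annotation the authors used.

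Low values were whole multiples of the worth of 1 read, so the depth could be worked back. With GENCODE exon lengths, between 92.3% and 93.4% of the values under 200 reads came out whole within 0.02 of a read. Of the values of 1000 reads or more, at least 97.2% were whole within 0.05. The reads at genes recovered in this way were 38.1, 37.8 and 32.6 M (1e6) in control 1, 2 and 3. They were 33.8, 33.4 and 33.2 M in treated 1, 2 and 3. Whole reads were recovered in all 6 libraries for 25156 genes. PCR reads without molecular identifiers are not independent molecules, so these numbers bear on counting error only.

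The deposited FPKM had been scaled between libraries and not by the total of each library. Median-of-ratios factors computed from the FPKM over the 13770 genes above 0 in every library were 1.01 in each library, with a spread of 1.32e-09. The library size implied by the values, divided by the recovered total, was 0.822, 0.839 and 0.719 in the control libraries and 1.33, 1.32 and 1.33 in the treated ones. Column totals of the deposited FPKM were correspondingly 451310, 450410 and 532580 in control 1, 2 and 3, and 236560, 241950 and 235760 in treated 1, 2 and 3. This scaling holds the typical gene level between groups, and a gene is read as higher or lower relative to it.

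The test was limma 3.58.1 in R 4.3.3 with a trended prior variance, on log2(FPKM + 1), for the 11118 genes at 1 FPKM or more in at least 3 of the 6 libraries, with group as the only term. A count model had been chosen for the event that the deposited values were counts, and the limma test for the event that they were not. Benjamini-Hochberg adjustment covered all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values, so fold changes between mean FPKM are also given. Values are means ± SD over 3 samples unless stated otherwise, and log2 fold changes are treated over control with their standard error.

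Before the data were examined, 36 gene lists were fixed, covering stress responses, cell death, metabolism, cell cycle, immune signalling, matrix and epithelial genes, signs of RNA quality and markers of other cell types. The 32 lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. The genes named were also fixed by rule. They are the 5 largest rises and 5 largest falls among called genes with non-overlapping groups and a mean of at least 5 FPKM, leaving out predicted models and mitochondrial genes. The rule adds the rising and the falling member with the smallest p of each main list (or the 2 with the smallest p where all moved one way) and Hmox1, Hspa1a, Mt1, Ddit3, Cdkn1a and Gpx4. Any other gene or family named was picked after its values were seen.

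The procedure was tested on simulated data for this comparison, with the 11118 genes and 200 of them changed in each of 5 runs. It recovered 63.2% of genes changed by 1 and 86.2% of genes changed by 2 on the log2 scale. Of the simulated calls, 6.34% were false with equal spread in both groups. With the unequal spreads of the real libraries 20.5% were false, and 15.9% with sample weights per group. These shares do not carry over to the real calls, which cover far more genes. The simulated groups also had no difference in composition. A simulated moved list was called in 5 of 5 runs and 0 of 150 unchanged lists were. The simulated genes were drawn independently, so this does not test false calls of lists whose genes vary together. In the real lists the estimated correlation reached 0.907.

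Alternatives chosen before the data were examined were other scalings, filters, pseudocounts and thresholds, the replicate number as a block, limma-voom on the recovered reads, and leaving out each sample. Further alternatives were added after the data were seen. These were TMM factors on the recovered reads, sample weights per group, quantile normalization, removal of the trend of values with GC content and length (with and without mean level, by splines with 5 degrees of freedom), and leaving out control 1 and control 3. The last leaves control 2 alone against 3 treated samples, with the spread taken from the treated samples only, so its values are given and its calls are not used. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.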

Results

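The transcriptome of 4T1 mouse mammary carcinoma cells was compared between 3 control samples and 3 samples that received Au/MoS2/Bi2S3 particles and near-infrared (NIR) light. The particles are a heterojunction material made for combined photothermal and photodynamic treatment of tumours. Treated cells were grown for 24 h, given 125 µg/mL of particles overnight, irradiated for 8 min and washed after 24 h more. The question the design implies is which transcripts differ after the combined treatment. Cells given particles or light alone were not analysed here. Each sample had between 32.6 and 38.1 M reads at genes (M, 1e6), worked back from the deposited FPKM.

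NRF2 targets were higher and cholesterol synthesis genes lower as lists in treated cells, although with an estimated correlation neither was called (camera adjusted p = 0.161 and 0.143). Enzymes that remove reactive oxygen species were lower as a list, a call lost with an estimated correlation (camera adjusted p = 0.194) and under 6 further alternatives. The transcript of Hmox1, the inducible heme oxygenase, was 5.61-fold higher, at 155.6 ± 1.80 FPKM (SD, n = 3) against 27.8 ± 9.27. Nqo1, a quinone reductase, was 9.05-fold higher and Srxn1, which encodes sulfiredoxin, was 7.50-fold higher. Mvd, which encodes an enzyme of the mevalonate pathway, was 10.7-fold lower. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, and Mmp9, a secreted matrix protease, were 5.39-fold and 7.74-fold lower.

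By limma, 3099 of 11118 genes were higher and 3141 lower in treated cells at an adjusted p under 0.05, which is 56.1% of the genes tested. Of these, 1089 were higher and 1504 lower by 2-fold or more. An unadjusted p under 0.05 was reached by 6899 genes. Counts of called list members given below are to be read beside the 56.1% called among all genes tested. Every treated sample lay above every control sample for 3740 genes and below for 3786, together 67.7% of the genes, where chance gives 10%. The split of calls rested on the scaling. With scaling by library size only, 6310 genes were higher and 1111 lower, 85.0% of the calls higher against 49.7%, with the median of all genes at a log2 fold change of 0.61, against which single genes and lists under that scaling are to be read. With a minimum of 5 FPKM 1385 genes were higher and 2516 lower. Without treated 1, 2 or 3 the calls fell to 1575, 1597 or 1542 higher and 2068, 2136 or 2011 lower. The filter still asked for 3 libraries, so genes at 1 FPKM only in treated samples dropped out and 10353, 10356 or 10366 were tested. Without control 1 calls fell to 2564 higher and 2251 lower. They rose to 3578 and 3443 without control 2, and to 3637 and 3585 without control 3.

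The control libraries differed in composition from the treated ones and from each other. Control 2 correlated with treated libraries (Pearson r between 0.906 and 0.911 across genes) about as well as with control 3 (0.911), and control 1 lay between the other 2 controls for 65.6% of genes. Genes above 0 FPKM numbered 18115, 18988 and 15829 in control 1, 2 and 3, against 22088, 21821 and 22047 in treated 1, 2 and 3. The 100 most abundant genes held 34.1%, 33.0% and 36.1% of the recovered reads at genes in control libraries and 19.1%, 19.4% and 19.0% in treated ones. The median SD between replicates was 0.27 on the log2 scale in controls and 0.07 in treated samples. Log2 fold changes fell with mean level, with a rank correlation across genes of -0.434, genes not being independent replicates. The median log2 fold change was 0.52 in the least abundant 10% of the tested genes and -0.93 in the most abundant 10%. Scarce genes at 1 FPKM only in the treated libraries pass the filter, which can raise the first of these medians.

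**Figure D1:**
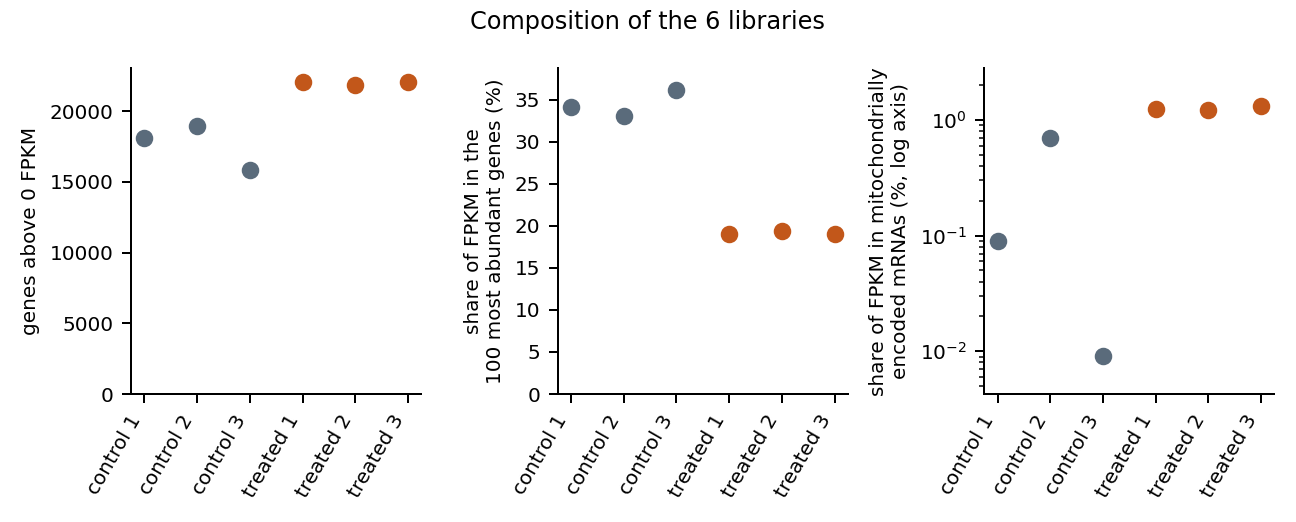
Each point is 1 library, with control libraries in grey and treated libraries in orange. The panels show genes above 0 FPKM, the percentage of recovered reads in the 100 most abundant genes, and that in mitochondrially encoded mRNAs on a log axis. The axis titles of the percentage panels say FPKM, but the values are shares of reads. Control libraries hold between 15829 and 18988 genes and treated libraries between 21821 and 22088.

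**Figure D2:**
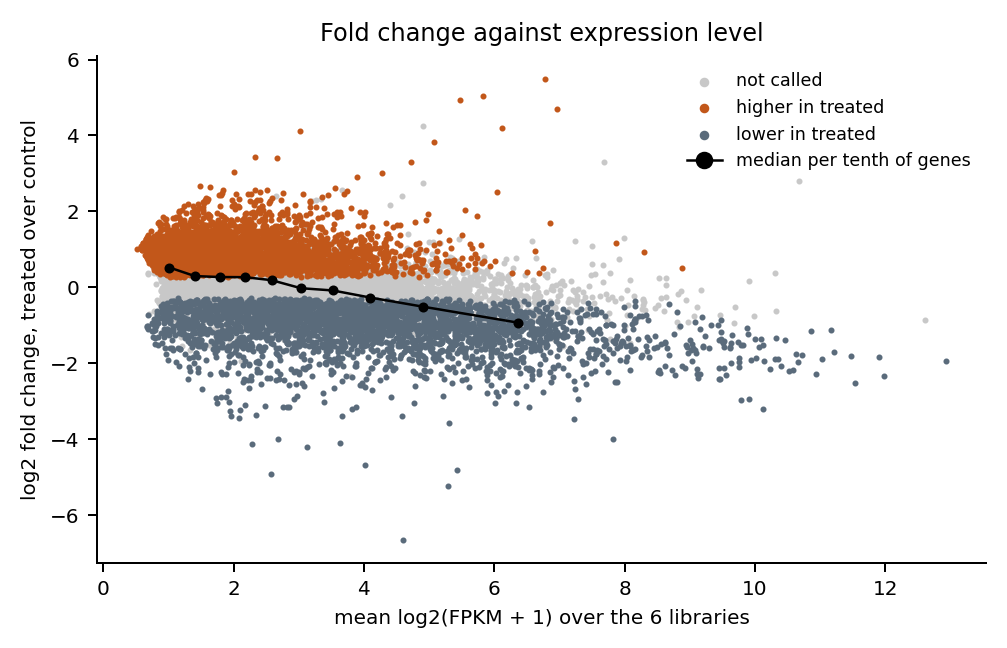
Each point is 1 of the 11118 genes tested, with its mean log2(FPKM + 1) over the 6 libraries on the x axis and its log2 fold change on the y axis. Orange genes were called higher and dark grey genes lower in treated cells, and the black line joins the medians of 10 equal groups of genes, from 0.52 at the lowest level to -0.93 at the highest.

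The largest rises chosen by the fixed rule were Angptl4, Nqo1, Egr1, Srxn1 and Chst12. Angptl4 (chromosome 17, 33773750 to 33781830), a secreted inhibitor of lipoprotein lipase, rose from 0.967 ± 0.319 to 19.6 ± 0.962 FPKM (log2 fold change 3.40 ± 0.15 SE, limma adjusted p = 0.000136). Nqo1 (chromosome 8, 107388225 to 107403206) rose from 9.04 ± 6.44 to 81.8 ± 1.10 FPKM (3.30 ± 0.53 SE, limma adjusted p = 0.00301), and its log2 fold change was 2.33 against control 2 alone. Egr1, an immediate early transcription factor, went from 0.417 ± 0.250 to 10.5 ± 0.560 FPKM, on 26 to 100 reads per control library. Chst12, a carbohydrate sulfotransferase, went from 1.45 ± 0.809 to 13.0 ± 0.574 FPKM. As the rule requires, all 5 were higher in 3 of 3 treated samples than in any control.

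The largest falls were Mir1938, Cdk19os, Snord55, Hist1h4i and Gadd45g, and some of these loci overlap another gene. Gadd45g (chromosome 13, 51846678 to 51848468), a growth arrest and DNA damage inducible gene, fell from 569.4 ± 353 to 44.2 ± 1.56 FPKM. Its log2 fold change was -3.46 ± 0.45 SE (limma adjusted p = 0.00147), and -1.99 with the trend for GC content, length and level removed. The histone gene Hist1h4i was 13.1-fold lower (limma adjusted p = 0.000136). Mir1938 (chromosome 12, 40222712 to 40222811, minus strand) lies in an intron of Ifrd1 on the same strand and overlaps an exon of the antisense gene Gm7008. It went from 311.4 ± 268 to 1.495 ± 0.777 FPKM, on 346 to 1443 reads per control library, while Ifrd1 stood at 25.6 and 27.1 FPKM. Cdk19os (chromosome 10, 40348508 to 40350103, minus strand) overlaps exons of Cdk19 on the plus strand, so its values are uncertain without a stated strand setting. It went from 43.5 ± 39.3 to 0.0931 ± 0.0406 FPKM, on 390 to 2297 reads per control library and 3 to 7 per treated one, while Cdk19 stood at 6.40 FPKM in controls and 13.4 in treated samples.

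Among NRF2 antioxidant targets, 17 of 30 measured genes rose, 4 fell and 9 were not called, with the same counts adjusted over the list alone. The list moved up against all other genes (median log2 fold change 0.66, camera adjusted p = 0.00337), but not with an estimated correlation (camera adjusted p = 0.161 with an estimated correlation). The members that rose included Hmox1 (chromosome 8, 75093621 to 75100589, log2 fold change 2.50 ± 0.26 SE, limma adjusted p = 0.000698). Srxn1 rose from 3.74 ± 0.607 to 28.1 ± 0.231 FPKM, and Slc7a11, the cystine importer, from 0.190 ± 0.0655 to 3.27 ± 0.142. The 4 that fell were Tkt, a transketolase of the pentose phosphate pathway (82.9 to 31.6 FPKM), Txn1, Abcc1 and Ftl1. Tkt was not called with scaling by library size only (limma adjusted p = 0.0579). With the trend for GC content, length and level removed, the median of the list was 1.13.

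Cholesterol synthesis genes fell as a group, with 22 of 25 members lower, 0 higher and 3 not called, and 23 lower adjusted over the list alone. Their median log2 fold change was -1.97 (camera adjusted p = 3.43e-11), and camera adjusted p = 0.143 with an estimated correlation. Mvd (chromosome 8, 122433601 to 122443422) fell from 28.8 ± 1.51 to 2.68 ± 0.328 FPKM (log2 fold change -3.02 ± 0.11 SE, limma adjusted p = 0.000136). Fdft1, which encodes squalene synthase, was 4.85-fold lower. With scaling by library size only, where the median of all genes stood at 0.61, the median of the list was -1.29. Fatty acid synthesis genes went the same way, with 7 of 13 lower and 0 higher, also adjusted over the list alone (median -0.81, camera adjusted p = 0.00524). Their camera adjusted p = 0.234 with an estimated correlation.

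**Figure D3:**
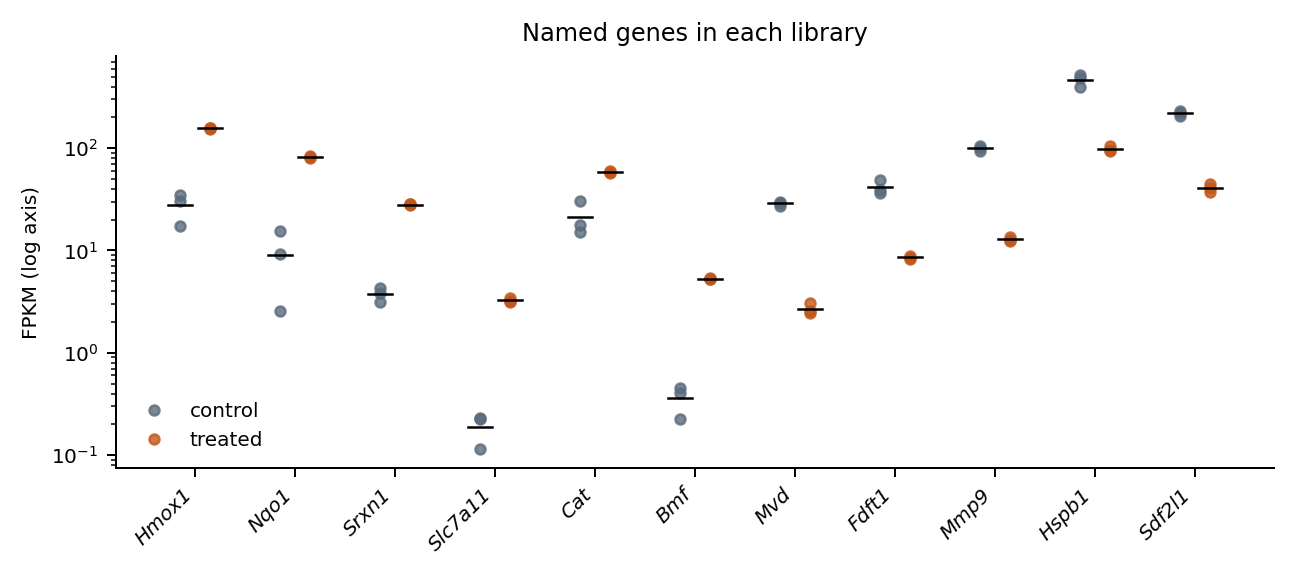
Each point is 1 library's FPKM on a log axis for 11 of the named genes, with controls in grey, treated samples in orange and the mean of 3 samples as a bar. Hmox1 lies between 17.4 and 35.2 FPKM in control libraries and between 153.7 and 157.3 in treated ones, and Mvd between 27.1 and 29.9 in controls and between 2.42 and 3.05 in treated libraries.

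Genes of the unfolded protein response were mostly lower, with 14 of 22 members fallen, 1 risen and 7 not called, and 15 fallen and 1 risen adjusted over the list alone. Their median log2 fold change was -1.38 (camera adjusted p = 0.00019; camera adjusted p = 0.161 with an estimated correlation) and -0.47 with quantile normalization. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell from 220.2 ± 12.5 to 40.9 ± 3.64 FPKM (log2 fold change -2.40, and -1.20 with the trend for GC content, length and level removed). Xbp1, a transcription factor of this response, was the member that rose, from 23.2 ± 7.43 to 37.5 ± 1.42 FPKM (limma adjusted p = 0.0323). It was not called without control 1 or control 2, or without treated 1, 2 or 3, or with no filter on low values (limma adjusted p between 0.05 and 0.106). Integrated stress response genes went both ways, with 10 of 31 higher and 8 lower, 11 and 8 adjusted over the list alone (median 0.07, camera adjusted p = 0.716). That list was called higher with quantile normalization (median 0.34, camera adjusted p = 0.0296) and with the trend for GC content, length and level removed (0.40, camera adjusted p = 0.0229). Cebpg, of that list, was 2.09-fold lower, and with scaling by library size only it was not called (limma adjusted p = 0.0855). Ddit3, which encodes CHOP, stood at 19.1 ± 6.82 FPKM in controls and 18.4 ± 0.742 in treated samples (log2 fold change 0.01 ± 0.26 SE, limma adjusted p = 0.97).

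Enzymes that remove reactive oxygen species were lower for 10 of 19 members and higher for 1, with 11 and 1 adjusted over the list alone (median -0.62, camera adjusted p = 0.0284; camera adjusted p = 0.194 with an estimated correlation). Cat, the catalase gene, was the member that rose, from 21.1 ± 7.94 to 58.2 ± 1.56 FPKM. Prdx4, a peroxiredoxin of the secretory pathway, fell from 105.9 ± 11.9 to 28.7 ± 2.87 FPKM. The call of this list was lost without control 2 (median -0.58, camera adjusted p = 0.0592), without treated 1 (-0.63, 0.0533) or treated 3 (-0.54, 0.0607), and with the GC and length trend removed (-0.48, 0.0531). It was also lost with quantile normalization (-0.39, camera adjusted p = 0.212) and with the trend for GC content, length and level removed (-0.38, 0.254). Gpx4, the lipid peroxide reductase, fell from 222.7 ± 57.8 to 115.4 ± 12.8 FPKM (log2 fold change -0.92 ± 0.21 SE, limma adjusted p = 0.0121). Without treated 3 its adjusted p by limma was 0.0595, and it was not called under library size, quantile, or GC and length settings, with log2 fold changes between -0.41 and 0.30. Ferroptosis regulators, which include Gpx4, Slc7a11 and Fdft1, were higher for 6 of 27 and lower for 11, 7 and 12 adjusted over the list alone (camera adjusted p = 0.322).

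Heat shock and chaperone genes split, with 7 of 24 higher and 6 lower, also adjusted over the list alone (median -0.17, camera adjusted p = 0.602). Bag3, a co-chaperone, rose from 22.8 ± 3.37 to 52.1 ± 2.29 FPKM, and the small heat shock gene Hspb1 fell from 465.1 ± 61.0 to 98.1 ± 5.83. The log2 fold change of Hspb1 was -2.23, and -0.59 with the trend for GC content, length and level removed. Hspa1a was below the filter and was not tested. It stood at 0.140, 0.0425 and 0 FPKM in control 1, 2 and 3 (13, 4 and 0 reads) and at 0.562, 0.465 and 0.389 in treated 1, 2 and 3 (75, 61 and 51 reads). In control 3, 0 reads allow up to 0.0431 FPKM (3 reads). These values are uncertain because Hspa1a has a near-identical neighbour, Hspa1b.

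Metal response genes were higher for 7 of 12 and lower for 2, 7 and 3 adjusted over the list alone (median 0.74, camera adjusted p = 0.282). The metallothionein gene Mt1 rose from 166.3 ± 69.4 to 348.9 ± 18.8 FPKM (log2 fold change 1.16 ± 0.33 SE, limma adjusted p = 0.0242). Mt1 was not called without control 1 (limma adjusted p = 0.0615) or without treated 1, 2 or 3 (0.0729, 0.0803 and 0.0741). Nor was it called with no filter on low values (0.0625). Under these alternatives its log2 fold change stayed between 1.113 and 1.225. Against control 2 alone its log2 fold change was 0.58. Cox17, a copper chaperone, rose from 0.252 ± 0.0727 to 1.58 ± 0.151 FPKM. The members that fell were Slc39a4, a zinc transporter, and Slc31a1, the copper importer (23.9 ± 5.12 to 15.6 ± 0.252 FPKM, limma adjusted p = 0.0297). Slc31a1 was not called without control 1 (0.092) or without treated 1, 2 or 3 (0.098, 0.1 and 0.0925), nor under 6 further alternatives.

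Targets of p53 were higher for 12 of 25 and lower for 4, also adjusted over the list alone (median 0.40, camera adjusted p = 0.0895). The list was called without treated 2 (camera adjusted p = 0.0493) or treated 3 (0.0484), with a minimum of 5 FPKM (0.03), with quantile normalization (0.0232) and with the trend for GC content, length and level removed (0.0161). Tigar, a fructose bisphosphatase, rose from 0.144 ± 0.146 to 1.91 ± 0.0760 FPKM, on 35, 12 and 2 reads in control 1, 2 and 3. The 4 that fell were Bbc3, Pmaip1, Gdf15 and Ddit4, of which Bbc3 and Pmaip1 encode BH3-only cell death proteins. Bbc3, also known as Puma, was 3.62-fold lower, with a log2 fold change of -1.75, and -0.61 with the same trend removed. Cdkn1a, the p21 gene, stood at 67.7 ± 12.3 and 87.2 ± 2.59 FPKM (log2 fold change 0.37 ± 0.15 SE, limma adjusted p = 0.0807), higher in 3 of 3 treated samples. Without control 3 it was called (0.51, limma adjusted p = 0.00449), as it was under 5 other alternatives that leave at least 2 controls. Apoptosis genes were higher for 7 of 35 and lower for 6, also adjusted over the list alone (median 0.02, camera adjusted p = 0.716). Bmf, a BH3-only gene, rose from 0.363 ± 0.122 to 5.29 ± 0.0618 FPKM. Of 11 necroptosis and pyroptosis genes, Ripk1, Mlkl, Casp4, Gsdme and Nlrp3 rose and Gsdmd fell (median 0.27, camera adjusted p = 0.322, 5 and 1 adjusted over the list alone).

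Called genes of oxidative phosphorylation fell in the nuclear list and rose in the mitochondrially encoded list, and the lists were not tested against each other. Of 75 nuclear genes of oxidative phosphorylation, 49 fell and 0 rose, 51 and 0 adjusted over the list alone (median -0.85, camera adjusted p = 2.05e-07; camera adjusted p = 0.161 with an estimated correlation). Ndufb10, a subunit of respiratory complex I, fell from 127.1 ± 5.35 to 43.5 ± 3.00 FPKM and Atp5l, of the ATP synthase, from 14.6 ± 0.725 to 4.55 ± 0.510. The call was lost with the trend for GC content, length and level removed (median -0.19, camera adjusted p = 0.166). Of 12 mitochondrially encoded mRNAs, 9 rose and 0 fell, 10 and 0 adjusted over the list alone (median 3.42, camera adjusted p = 0.00843; camera adjusted p = 0.527 with an estimated correlation). They held 0.0891%, 0.701% and 0.00902% of the recovered reads at genes in control 1, 2 and 3 and between 1.21% and 1.32% in treated samples. Their median was 1.13 against control 2 alone, and with scaling by library size only the list was not called although its median was 4.01 (camera adjusted p = 0.297). Glycolysis genes were higher for 4 of 22 and lower for 9, also adjusted over the list alone (median -0.31, camera adjusted p = 0.199). They were called lower with no filter on low values (-0.31, camera adjusted p = 0.0277) and higher with quantile normalization (0.33, camera adjusted p = 0.0393). Hk2, a hexokinase, rose from 4.68 ± 1.59 to 20.01 ± 0.517 FPKM. Eno2, an enolase, fell from 17.4 ± 0.759 to 8.14 ± 0.0622, and was not called with scaling by library size only (limma adjusted p = 0.0527). Hypoxia response genes were higher for 7 of 22 and lower for 9, 7 and 10 adjusted over the list alone (camera adjusted p = 0.602).

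Cytosolic ribosomal protein genes were lower for 56 of 75 and higher for 0, also adjusted over the list alone (median -1.52, camera adjusted p = 6.68e-12; camera adjusted p = 0.161 with an estimated correlation). They held between 15.9% and 16.2% of the recovered reads at genes in control libraries and between 7.44% and 8.33% in treated ones. The call was lost with quantile normalization (median -0.10, camera adjusted p = 0.16) and with the trend for GC content, length and level removed (-0.31, camera adjusted p = 0.0992). Ribosome biogenesis genes moved the other way, with 20 of 36 higher and 3 lower, also adjusted over the list alone (median 0.60, camera adjusted p = 0.00337; camera adjusted p = 0.161 with an estimated correlation). The 3 that fell were Fbl, Ncl and Npm1, abundant nucleolar proteins. Proteasome genes were higher for 4 of 32 and lower for 13, also adjusted over the list alone (median -0.35, camera adjusted p = 0.186). They were called lower with no filter on low values (-0.35, camera adjusted p = 0.00804) and higher with quantile normalization (0.39, camera adjusted p = 0.0393).

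**Figure D4:**
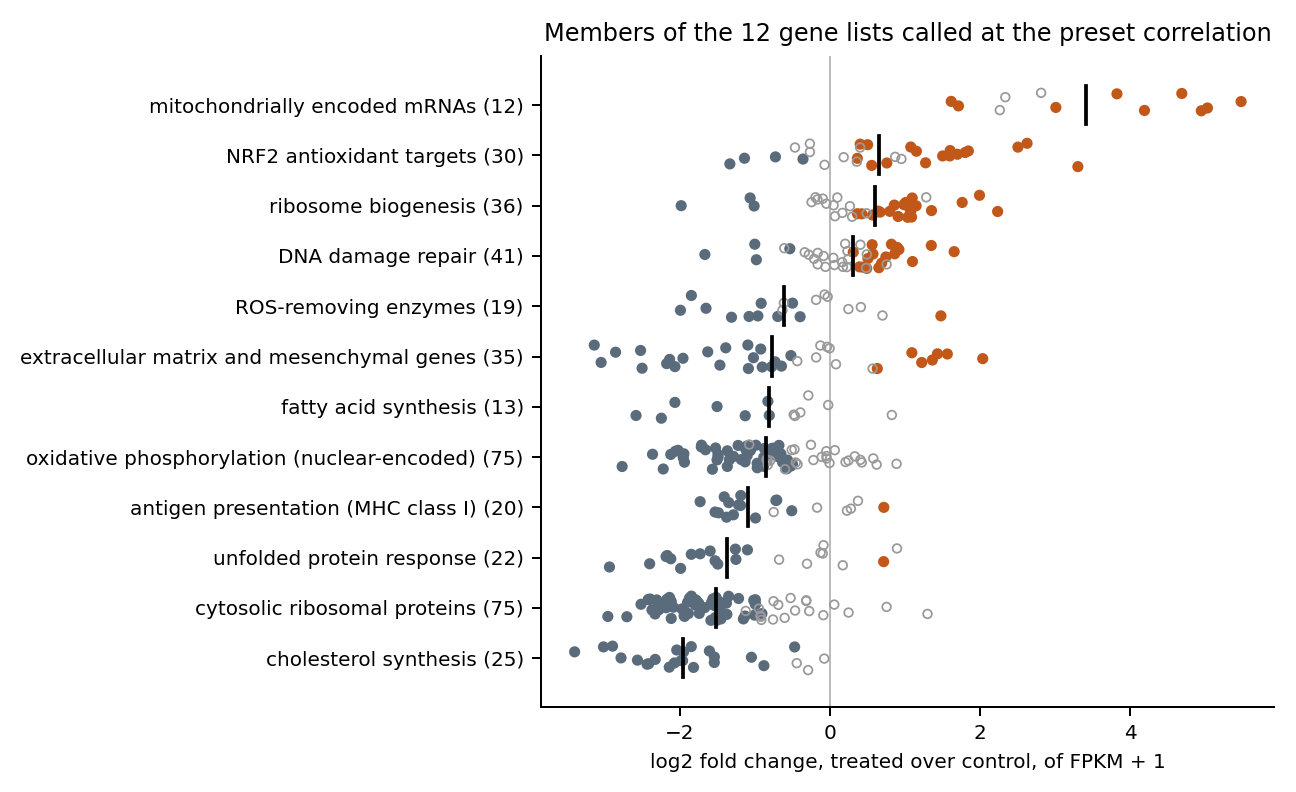
Each point is the log2 fold change, treated over control, of 1 tested member of the 12 lists called at the preset correlation. Orange and dark grey points were called higher and lower, open points were not called, black bars are medians, and the number of members stands in parentheses. Medians run from -1.97 for cholesterol synthesis to 3.42 for mitochondrially encoded mRNAs.

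Matrix and mesenchymal genes were lower for 21 of 35 and higher for 7, also adjusted over the list alone (median -0.78, camera adjusted p = 0.0205; camera adjusted p = 0.231 with an estimated correlation). Mmp9 (chromosome 2, 164940780 to 164955850) fell from 99.2 ± 5.11 to 12.8 ± 0.502 FPKM (log2 fold change -2.86 ± 0.10 SE, limma adjusted p = 0.000136). Zeb2, a transcription factor of mesenchymal cells, rose from 0.645 ± 0.0689 to 2.50 ± 0.0260 FPKM. The call of the list was lost with quantile normalization (median -0.17, camera adjusted p = 0.278) and with the trend for GC content, length and level removed (-0.25, camera adjusted p = 0.254). Of 4 fibroblast markers measured, Col1a1, Col3a1 and Fbln1 fell and Pdgfra was not called, and 2 of these collagens are also in the matrix list. Col1a1 stood at 369.6 FPKM in controls and 30.2 in treated samples. The macrophage markers Cd14 and Cd68 were not called, and of 3 endothelial markers Plvap fell while Cdh5 and Egfl7 were not called. Of 15 lymphocyte markers 0 passed the filter, with a highest group mean of 0.345 FPKM.

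Epithelial genes split, with 4 of 11 higher and 5 lower, 5 and 5 adjusted over the list alone. Their median was 0.05, their mean -0.16 and the camera direction up (camera adjusted p = 0.988). Tjp1, of tight junctions, rose from 4.39 ± 0.565 to 18.6 ± 1.33 FPKM, as did Grhl2, Dsp and Pkp3. Epcam, an epithelial adhesion gene, fell from 4.99 ± 0.673 to 0.896 ± 0.117 FPKM, as did Krt8, Krt18, Krt19 and Elf3.

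Called cell cycle genes went in both directions, as did called genes in general. Of 43 genes of DNA replication and G1/S, 11 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.322). Pole, a replicative polymerase, rose from 0.322 ± 0.0725 to 1.44 ± 0.0780 FPKM, and was not called with the trend for GC content, length and level removed (limma adjusted p = 0.0648). Gins2, of the replicative helicase, fell from 4.95 ± 0.847 to 2.59 ± 0.146 FPKM and was not called with scaling by library size only (limma adjusted p = 0.458). Of 50 mitotic genes, 12 rose and 13 fell, also adjusted over the list alone, with a median of 0.11, a mean of -0.004 and a camera direction down (camera adjusted p = 0.988). The mitotic transcription factor Foxm1 was 1.82-fold higher and the centromeric histone gene Cenpa 2.80-fold lower. DNA damage repair genes were higher for 17 of 41 and lower for 4 (Msh6, Ung, Xpa and Ddb1), also adjusted over the list alone (median 0.31, camera adjusted p = 0.0328; camera adjusted p = 0.19 with an estimated correlation). That call was lost without control 2 (median 0.385, camera adjusted p = 0.0928), control 3 (0.286, 0.0539) or treated 1 (0.215, 0.0533). It was also lost under 5 further alternatives, with medians from -0.03 to 0.426, the highest with limma-voom. Replication-dependent histone genes were higher for 1 of 10 (Hist1h2bc) and lower for 6, also adjusted over the list alone (median -1.05, camera adjusted p = 0.0667). Without control 1 or control 3 that median was -0.04 or -0.02. The list was called lower with library size only (camera adjusted p = 0.00254), with no filter on low values (0.000312) and with the replicate block (0.0468).

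Immune signalling genes also went both ways. NF-kB targets and cytokines were higher for 5 of 23 (Nfkbie, Ccl2, Csf1, Lif and Birc3) and lower for 7, also adjusted over the list alone. Their median was 0.07, their mean 0.05 and the camera direction down (camera adjusted p = 0.988). Birc3, an inhibitor of apoptosis gene, rose from 0.228 ± 0.0853 to 2.14 ± 0.212 FPKM, and the transcription factor Irf1 fell from 20.04 ± 2.35 to 7.80 ± 0.205. Type I interferon genes were higher for 10 of 21 and lower for 3 (Ifi35, Bst2 and Ifitm3), also adjusted over the list alone (median 0.29, camera adjusted p = 0.186), and with no filter on low values that list was called higher (camera adjusted p = 0.0384). Ifih1, the RNA sensor MDA5, rose from 0.549 ± 0.101 to 2.03 ± 0.145 FPKM. Bst2, a surface antiviral protein, fell from 78.4 ± 4.73 to 45.8 ± 4.76 FPKM, and stood at a log2 fold change of 0.40 (limma adjusted p = 0.0242) with the trend for GC content, length and level removed. It was not called with library size only (limma adjusted p = 0.833), with quantile normalization (0.829) or with the GC and length trend removed (0.536). Antigen presentation genes were lower for 14 of 20 and higher for 1 (Nlrc5), also adjusted over the list alone (median -1.09, camera adjusted p = 0.00337; camera adjusted p = 0.331 with an estimated correlation). That call was lost with quantile normalization (median -0.34, camera adjusted p = 0.0744).

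Autophagy and lysosome genes were higher for 5 of 50 (Sqstm1, Ulk2, Atg7, Atg14 and Mitf) and lower for 15, 4 and 13 adjusted over the list alone (median -0.07, camera adjusted p = 0.147). The list was called lower with no filter on low values (camera adjusted p = 0.00306). Mitf, a transcription factor, rose from 0.915 ± 0.0652 to 3.17 ± 0.377 FPKM, and Npc2, a lysosomal sterol carrier, fell from 348.4 ± 31.5 to 102.0 ± 3.15. Immediate early genes were higher for 5 of 25 (Fosl1, Fosl2, Egr1, Egr3 and Dusp5) and lower for 12, also adjusted over the list alone (median -0.72, camera adjusted p = 0.0929). That list was called lower without treated 2 (camera adjusted p = 0.0474), with library size only (0.0188) and with no filter on low values (0.00524). Of 5 nuclear-retained long RNAs, Malat1, Neat1 and Gas5 fell, also adjusted over the list alone (median -0.59, camera adjusted p = 0.096), and with no filter on low values that list was called lower (camera adjusted p = 0.00858). Of 16 reference genes, Actb, Tbp and Polr2a rose and 7 fell, also adjusted over the list alone (median -0.29, camera adjusted p = 0.322).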

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

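The alternatives with TMM factors, sample weights, quantile normalization, removed trends, and without control 1 and control 3 were chosen after the data were seen. Median-of-ratios factors had already been applied to the deposited values, so that alternative moved nothing and tests nothing. DESeq2 was not run because the files hold FPKM. With library size only, calls were 6310 higher and 1111 lower, and 3257 and 424 at 2-fold, with the median of all genes at 0.61. Slc31a1 stood at 0.14 there, below that median. With a minimum of 5 FPKM, which tests fewer genes, 1385 were higher, 562 of them by 2-fold. At 2-fold, 1831 were higher with a pseudocount of 0.1 and 1862 with limma-voom, and with GC, length and level removed 786 were lower. At an adjusted p under 0.01, 1926 were lower. Leaving out single samples gave 1542 to 3637 higher and 2011 to 3585 lower calls, 704 to 1365 and 1245 to 1636 at 2-fold, and 3 to 5 lists higher and 7 to 9 lower. Lists called numbered 4 higher and 8 lower, against 0 and 0 with an estimated correlation, 11 and 18 with fry, 14 lower with no filter, 7 higher and 4 lower with quantile normalization, and 4 lower with GC, length and level removed. Reversals were Bst2 (0.033), Gpx4 (0.089), glycolysis (0.33) and proteasome (0.39) with quantile normalization, Bst2 (0.40) and Gpx4 (0.30) with GC, length and level removed, and Ddit3 (-0.45) without control 1 and control 3, which leaves 1 control and decides nothing. The cause of these changes was not tested, apart from the fewer genes or samples that some settings leave. The NRF2 rise and the cholesterol fall were called under each alternative that leaves at least 2 controls, except the estimated correlation, with medians between 0.47 and 1.34 and between -2.22 and -1.29. Depth limits genes such as Hspa1a, at 0 to 13 reads in controls. Among the named rises, Egr1, Slc7a11, Cox17, Tigar, Bmf, Mitf, Pole, Birc3, Ifih1 and Zeb2 were under 1 FPKM in every control. They passed the filter only through treated samples. Loss of scarce molecules from the controls, which stays open below, could enlarge such rises and was not tested for them.

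The replicate numbers did not pair the samples. The deviations of same-numbered samples from their group means correlated at -0.05, -0.11 and -0.14 across genes. With the replicate block, 2618 genes were higher and 2669 lower, and 1092 and 1509 at 2-fold, with 4 lists higher and 9 lower.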

Other observations

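Of 217 zinc finger genes with Zfp symbols, a family picked after its values were seen, 135 rose and 20 fell in treated cells (median log2 fold change 0.72). With the trend for GC content, length and level removed 79 rose and 30 fell (0.18). Without treated 1, 2 or 3 only 145 members passed the filter, and 48, 52 or 49 of them rose (median 0.314, 0.352 or 0.358). Members at 1 FPKM only in treated samples dropped out there, because the filter asks for 3 libraries. Without control 1, 2 or 3 the median of the Zfp genes was 0.715, 0.738 or 0.65. Collagen genes went the other way, with 12 of 14 lower and 1 higher (median -1.65, and -0.93 with the same trend removed). Of 21 small nucleolar RNAs with Snord symbols, 11 fell and 0 rose (median -1.49). Only 5 of 21 fell with the same trend removed (-0.85), and 5 of 19 without control 1. Processed pseudogenes, which share sequence with their parent genes, were lower for 310 of 685 and higher for 20 (median -0.69). With the GC and length trend removed 148 fell and 81 rose (-0.10), and with level removed as well 159 fell and 50 rose (-0.22).

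The tests below were chosen after the results they bear on were seen, except the one that leaves out the 100 most abundant genes. For 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 6240 genes and the highest of the others 0, and at 2-fold 2593 against 0, each reached by 1 of the 10 splits. For lists the real split called 12 and so did another, so 2 of 10 splits gave as many. The other splits called between 3 and 12 lists.

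Control libraries held fewer genes and more of their reads in abundant genes. Lower depth argues poorly for this, since the mean total of reads in controls was 1.08 times that of treated samples and no pair of libraries went below 0.965. A few dominant genes would shift all other genes alike. Without the 100 most abundant genes the rank correlation of log2 fold change with level across genes was -0.421. Such a shift alone therefore does not account for that trend. The correlation was -0.434 with them, but leaving out 100 of 11118 genes can hardly move it, so the likeness of these values decides nothing. Whether dominant genes led to the fewer genes was not tested. Random loss of scarce molecules would keep summed levels equal. The sum over the 3706 least abundant tested genes, divided by that over the 1111 most abundant, was 3.07 times higher in treated samples (2.78 to 3.51 over pairs of libraries). Treated over control, the first sum was 1.26 (1.24 to 1.28) and the second 0.407. The filter admits scarce genes at 1 FPKM only in treated samples, which can raise the 1.26. The lower sum of the most abundant genes does not depend on that filter. It argues against such loss as the whole source of the larger share in abundant genes. For the fewer genes such loss stays open, because the share of genes without a read cannot decide it. Scarce tested genes stood higher in treated samples (median log2 fold change 0.52 in the least abundant 10%), a value that the filter can raise. Such a difference alone would leave fewer of them without a read there. Left-out controls were also scored on genes chosen from the other controls, and treated libraries on genes chosen from all controls. Genes of 10 to 40 reads in controls had no read in 9.64%, 8.61% and 28.8% of cases in control 1, 2 and 3 when left out of the choice, against 3.03% to 3.41% in treated libraries, a ratio of at least 2.53. Uneven amplification or RNA quality in the control libraries, and the treatment itself, stay open because each falls on the same 3 libraries.

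Of 12 mitochondrially encoded mRNAs 9 were lower in controls, and levels varied among controls, with mt-Nd1 between 0.268 and 208.4 FPKM in controls and between 674.3 and 763.7 in treated samples. Low GC content is not the whole source, since nuclear genes matched within 1 point of GC had a median log2 fold change of 0.344 against 3.42. The 0.344 covers the 10 mRNAs with at least 20 matched genes, and the 3.42 covers all 12. The mRNAs left out, mt-Nd3 and mt-Nd6, have the lowest GC content. For control 1 and control 2, loss of all mitochondrial RNA as the whole source is argued against by the mitochondrial rRNAs. Under the deposited scaling their log2 fold changes were -0.56 and -1.02, and at most 0.69 with 2 standard errors added. They held 0.0835% and 0.152% of the recovered reads in control 1 and 2, and 0.0598% to 0.0789% in treated samples. In control 3 they held 0.0331%, so such a loss stays open for that library. Among controls, the shares of the rRNAs and of the mRNAs were both highest in control 2 and lowest in control 3. A partial loss that varies between controls therefore stays open too. For 10 of 12 of these mRNAs the range among controls was as large as the difference between groups, which is consistent with a source that varies between control libraries and that the treatment does not set. A change caused by the treatment on top of that was not tested.

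The rise of NRF2 targets and the fall of cholesterol synthesis genes remained when the trend for GC content, length and level was removed. Their medians were then 1.13 and -1.87, each still called by camera at the preset correlation, which argues against that trend as the whole source. Against control 2 alone, without the 2 controls with the fewest genes, the medians were 0.812 and -1.82, but an arm of 1 library decides nothing. The share of those 2 controls in the changes, other differences between the 2 sets of libraries, and a response to particles or light stay open. Cells given particles alone or light alone, which were not analysed here, would be needed to part the last of these.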
